A study of Mus musculus with 7 samples.

How the data were processed

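Per the labels, RNA sequencing measured 7 samples of eGFP-positive pancreatic mesothelial (PanMeso) cells in 3 groups, namely parental cells (n = 3) and cells sorted from tumours made with BMFA3 (n = 2) or CT1BA5 (n = 2) pancreatic cancer cells. The labels' protocols describe culture at 33 °C in a medium with 400 nM hydrocortisone, 3.3 nM epidermal growth factor and 870 nM insulin, and a change to 37 °C for 3 days before use. RNA was extracted with the RNeasy Mini kit and libraries were made by standard Illumina methods, per the labels' protocols. The deposited file holds raw gene counts, as whole numbers for Ensembl mouse gene identifiers with a column for each sample. CASAVA, DESeq2 1.24.0 and the mm10 genome are named per the submitters' processing notes, which give them no role. The aligner, the counting tool, the annotation release and whether counting used strand are not given in the sources used here. Column totals are unequal, which fits raw counts.

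The table held 54532 genes, of which 54409 matched an identifier of GENCODE mouse release M21 (GRCm38), the source of symbols and coordinates, and 123 did not; 31634 had 0 counts in every library. Genes were kept with edgeR's filterByExpr by group (minimum count 10), which left 13784 genes with 99.9% of the counts. Counts were scaled by TMM (factors 0.897 to 1.08), and levels are given as CPM on those scaled library sizes, as mean ± SD. Within groups, libraries differed by 2.24 (BMFA3), 2.35 to 3.24 (parental) and 5.14 (CT1BA5) times the variance of sampling noise. Each library was treated as a sample, although the labels do not say whether replicates are separate cultures or tumours.

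Design, tests, gene lists and alternatives were chosen before the data were examined. A negative binomial model with the 3 groups was fitted in edgeR 4.0.16 (R 4.3.3) and tested by quasi-likelihood F tests with Benjamini-Hochberg adjustment at 0.05; the common biological coefficient of variation was 0.0830. The 4 comparisons were the mean of both sorted groups against parental, BMFA3 against parental, CT1BA5 against parental and CT1BA5 against BMFA3. All libraries share an estimate of the spread, as groups of 2 give little alone, and it may be too low for CT1BA5. Changes of more than 2-fold were tested with glmTreat.

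There were 29 gene lists: mesothelial identity, fibroblast and fibrillar matrix, myofibroblastic and inflammatory CAFs, MHC class II and class I presentation, T cell costimulatory and inhibitory ligands, interferon, NF-kB and IL-1, TGF-beta and glucocorticoid responses, matrix remodelling, complement, cell cycle, cholesterol synthesis, glycolysis and hypoxia, immediate early and heat shock genes, epithelial-mesenchymal transcription factors, and markers of 11 other cell types. Those cell types were macrophages, neutrophils, dendritic cells, lymphocytes, endothelium, tumour epithelium, acinar, islet and erythroid cells, pericytes and stellate cells, and adipocytes. Lists with at least 3 tested members (23 of 29) were tested with camera (limma 3.58.1, preset correlation 0.01), which compares a list with all other genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction and compares them with no other genes, were run beside it. For sorted against parental cells the estimated correlation was 0.75 for cholesterol synthesis. It was -0.034, 0.010 and -0.0084 for the myofibroblastic CAF, TGF-beta and glucocorticoid lists, near or below the preset value. A call lost with this setting thus need not mean that a list's genes were more correlated than preset.

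Named genes followed a fixed rule: 20 genes chosen in advance; per comparison the 10 higher and 10 lower genes (5 and 5 for a single tumour line) with the largest log2 fold change among genes past adjusted p 0.05, with a mean of at least 10 CPM, a symbol that is not a predicted gene and groups that do not overlap; and per list the 4 members with the smallest p. Other list members named as examples were chosen after their values were seen. A few genes that the rule names are not reported here. Of 196 named genes, 27 overlap another gene above 1 CPM; as counting by strand is not stated, values of genes such as Junb (with Prdx2), Dusp1 (Ergic1), Mcm7 (Cops6), Tgfb3 (Ttll5), Timp1 (Syn1), Gapdh (Iffo1), Cp (Hps3), Ctsw (Fibp), Cyp51 (Akap9), Vsir (Cdh23), Tap1 (Psmb9), Csf1r (Hmgxb3), Egfl7 (Agpat2), Alas2 (Apex2), Igtp (Irgm2), Slc39a2 (Mettl17) and Gbp4 (Gbp9) are uncertain to that extent. So are ribosomal protein, MHC class I and other multigene family members that share reads.

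A gene with 0 counts in a group was given a fold against a floor of 3 counts over the group, and with 1 to 3 counts a ratio with a 95% exact interval. Intervals and floors cover counting error only. Opposing scalings (RLE, library size alone), filters (none, or CPM of at least 1 in at least 2 libraries), adjusted p of 0.01, glmTreat, the replicate number as a block, each library left out, fits of only the groups compared, a 2-group fit of all sorted against parental libraries, limma-voom and DESeq2 1.42.0 were tried as alternatives. Leaving out genes linked to ribosomal RNA was added after the data were seen.

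The scripts were tested on simulated data with known changes. Among changed genes at 10 CPM or more, 59 of 59 with a 3-fold change were recovered in each comparison, and of 63 with a 1.5-fold change 63, 58, 56 and 52 for both groups, BMFA3, CT1BA5 and CT1BA5 against BMFA3, over 13186, 13181, 13166 and 13171 genes. False calls were 9 of 162, 11 of 154, 11 of 151 and 17 of 153. A planted list was recovered by camera, camera with an estimated correlation and fry in the comparisons of both groups with parental and of CT1BA5 with BMFA3. Of 20 unchanged lists, fry called 1 in the latter. Correlations of log2 fold change with transcript length across genes were -0.17, -0.053, -0.24 and -0.34 (Spearman) for both groups, BMFA3, CT1BA5 and CT1BA5 against BMFA3, and with GC content 0.14, 0.11, 0.16 and 0.14. The total of sequenced reads is not given in the sources used here.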

Results

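Gene expression was measured by RNA sequencing in 7 libraries of PanMeso cells, mouse mesothelial cells derived from the pancreas that carry enhanced green fluorescent protein (eGFP). Mesothelial cells form the sheet that lines the body cavities and covers the organs in them. The parental group (n = 3) was grown in culture. The other groups were eGFP-positive cells recovered by flow sorting from pancreatic tumours, which had formed after PanMeso cells were injected together with the pancreatic cancer cells BMFA3 (n = 2) or CT1BA5 (n = 2). The series concerns cancer-associated fibroblasts (CAFs) that arise from mesothelial cells, present antigen and act on regulatory T cells.

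Library totals were 10096839 to 19210598 counts in parental, 14792189 to 16501058 in BMFA3 and 14327365 to 16981596 in CT1BA5 libraries. Libraries of the same group lay close together, with a correlation of log2 CPM across genes of 0.989 to 0.993. That correlation was 0.919 to 0.923 between parental and BMFA3 libraries, 0.853 to 0.862 between parental and CT1BA5 libraries and 0.941 to 0.949 between the sorted groups. Genes are not independent replicates in these correlations. The first principal component held 75.8% of the variance and ordered the libraries as parental, BMFA3 and CT1BA5, and the second (15.6%) set BMFA3 apart. Cytosolic ribosomal protein genes took 4.37 to 5.04% of the counts in parental, 6.88 to 6.94% in BMFA3 and 8.55 to 9.86% in CT1BA5 libraries. Mitochondrially encoded genes took 0.416 to 0.466%, 0.789 to 0.853% and 0.936 to 1.04% in the same order. Genes linked to ribosomal RNA took 0.0426 to 2.35%, and this share varied within each group.

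**Figure D1:**
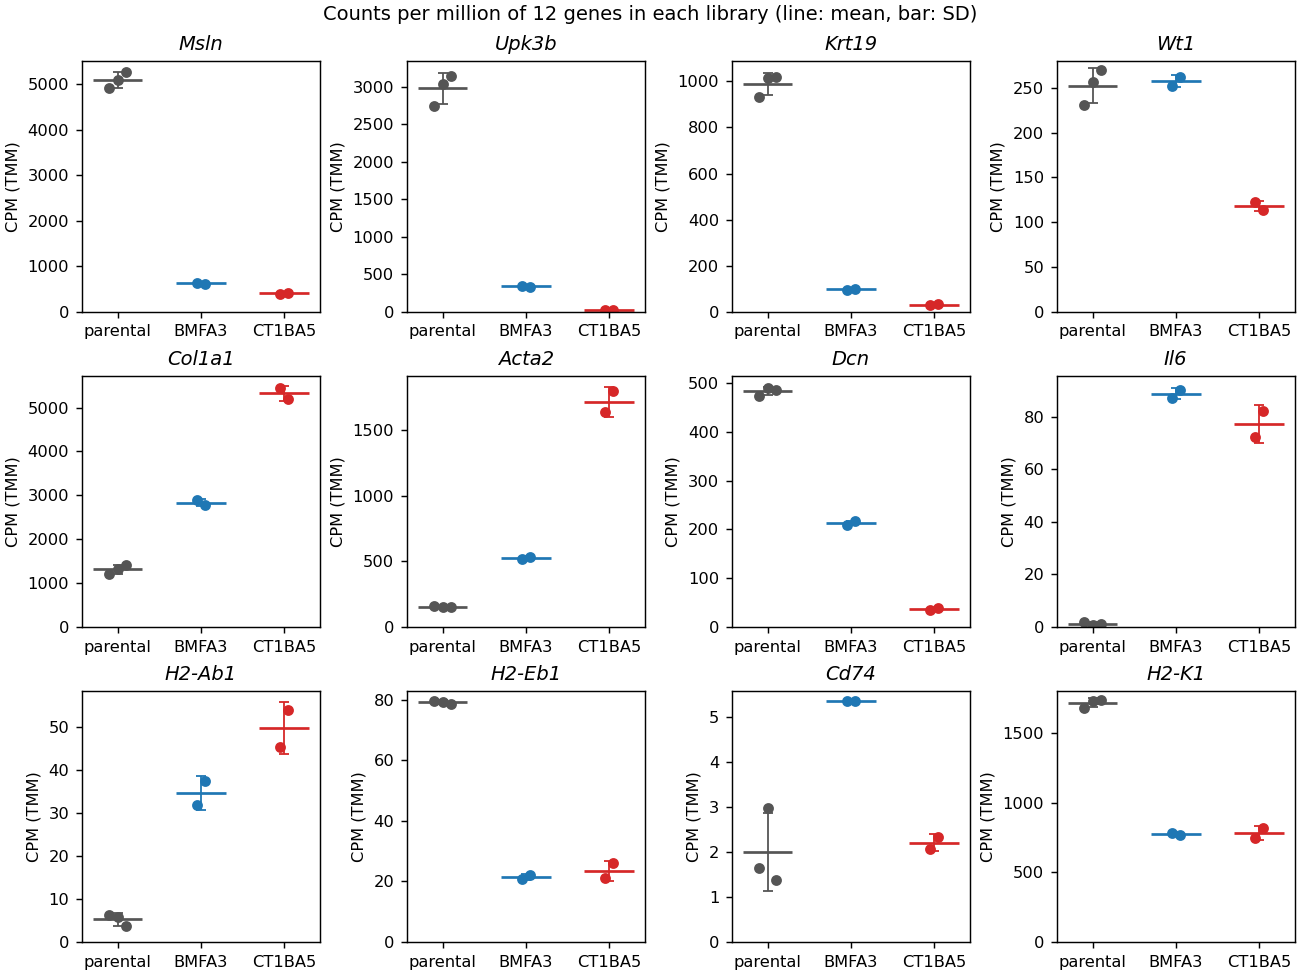
Normalised counts per library in CPM, on linear axes from 0, of 12 genes in parental, BMFA3 and CT1BA5 libraries, with the group mean as a line and the SD as a bar. Msln falls from 5093 CPM in parental to 624 and 409.5 CPM in BMFA3 and CT1BA5, while H2-Ab1 rises from 5.24 to 34.7 and 49.8 CPM.

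The first comparison asked how PanMeso cells taken from tumours differed from the cultured cells they came from, as the mean of both sorted groups against parental cells. Of the measured genes, 19 of 21 on the mesothelial identity list fell and 13 of 20 on the myofibroblastic CAF list rose. As groups these calls were lost with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.169 and 0.0637). Msln, which encodes the surface protein mesothelin, stood at 5093 ± 169.6, 624 ± 10.4 and 409.5 ± 13.3 CPM (mean ± SD; n = 3, 2 and 2) in parental, BMFA3 and CT1BA5 cells, and was 10.1-fold lower in sorted cells. Col1a1, the gene of the main chain of type I collagen, rose from 1308 ± 109 to 2835 ± 81.6 and 5328 ± 173 CPM, and Acta2, the gene of smooth muscle actin, from 154 ± 3.91 to 524 ± 12.3 and 1713 ± 112 CPM. Il6, an inflammatory cytokine gene, rose from 1.13 ± 0.643 to 88.7 ± 2.18 and 77.2 ± 7.24 CPM. Among genes of antigen presentation to helper T cells, H2-Ab1 rose 8.26-fold and H2-Eb1 fell 3.52-fold.

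On the GRCm38 (mm10) genome the genes followed most closely were Msln (ENSMUSG00000063011, chromosome 17, 25748613 to 25754378), Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) and Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590). For antigen presentation they were H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419), H2-Eb1 (ENSMUSG00000060586, chromosome 17, 34305867 to 34316674) and Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652). Log2 fold changes of sorted over parental cells were -3.33 ± 0.047 (SE) for Msln, 1.57 ± 0.054 for Col1a1, 2.62 ± 0.060 for Acta2, 3.05 ± 0.14 for H2-Ab1 and -1.82 ± 0.073 for H2-Eb1. With edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 3.5e-21, 1.8e-15, 3.8e-18, 2.5e-13 and 1.9e-14 in that order.

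Of 21 measured members of the mesothelial identity list, 2 rose and 19 fell (the same numbers adjusted over the list alone). Upk3b, a uroplakin of the mesothelial surface, stood at 2979.8, 339 and 20.4 CPM in parental, BMFA3 and CT1BA5 cells, and Krt19, a keratin of epithelial sheets, at 989, 97.2 and 30.8 CPM. Gpm6a, a membrane glycoprotein gene, stood at 631, 86.1 and 19.8 CPM. Wt1, a transcription factor of the mesothelium and called lower in CT1BA5 but not in BMFA3, fell less in the mean, with a log2 fold change of -0.53 ± 0.060 (SE). The members that rose were Pdpn, the podoplanin gene, and Aldh1a2, which encodes an enzyme that makes retinoic acid and went from 0.104 to 9.14 and 56.5 CPM. As a group the list fell (median log2 fold change -2.69, camera, Benjamini-Hochberg adjusted p = 6.1e-14, and adjusted p = 0.169 with an estimated correlation).

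The myofibroblastic CAF list, genes of contractile fibroblasts, had 20 measured members, of which 13 rose, 4 fell and 3 did not pass the test (14 higher and 4 lower adjusted over the list alone). Tnc, a matrix glycoprotein gene, stood at 27.0, 106 and 1368 CPM and Inhba, which encodes the activin A subunit, at 55.4, 128 and 877 CPM, while the member Col8a1, a collagen gene, fell. The list rose as a group (median 1.65, camera, Benjamini-Hochberg adjusted p = 2.5e-05, and adjusted p = 0.0637 with an estimated correlation). Among 16 genes that respond to TGF-beta, 14 rose and 2 fell (the same numbers adjusted over the list alone); the latter were the basement membrane collagen genes Col4a1 and Col4a2. Snai1, a transcription factor gene, stood at 6.59, 58.8 and 114 CPM. This list also rose (median 1.58, camera, Benjamini-Hochberg adjusted p = 1.0e-10, and adjusted p = 0.0576 with an estimated correlation). Of 23 matrix remodelling enzymes and their inhibitors, 15 rose and 8 fell (the same numbers adjusted over the list alone). Lox, which encodes a collagen cross-linking enzyme, stood at 770.1, 2879 and 7185 CPM, and Timp1, a metalloprotease inhibitor gene, at 167, 3202 and 5177 CPM; members that fell included Adamts1, Mmp3 and Timp2. Their group test was past the threshold (median 0.69, camera, Benjamini-Hochberg adjusted p = 0.00684, and adjusted p = 0.169 with an estimated correlation).

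The list of fibroblast and fibrillar matrix genes moved apart: of 20 measured members, 10 rose, 7 fell and 3 did not pass the test (the same numbers adjusted over the list alone). Col1a2 rose from 303 ± 12.3 to 1065 ± 25.6 and 1572 ± 19.9 CPM. Dcn, which encodes the matrix proteoglycan decorin, fell from 484 ± 8.18 to 213 ± 4.64 and 36.0 ± 2.90 CPM, and Col6a1 and Col6a2, genes of type VI collagen, fell by 2.73 and 2.78 on the log2 scale. This list as a group did not pass the test (median 0.69, camera, Benjamini-Hochberg adjusted p = 0.505).

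Of the 14 measured genes of inflammatory CAFs, 10 rose and 4 fell (the same numbers adjusted over the list alone). Has2, which encodes a hyaluronan synthase, stood at 6.03, 296 and 878 CPM, and the chemokine gene Ccl2 rose 3.90-fold. Cxcl12, a chemokine gene, fell from 46.4 ± 6.22 to 26.1 ± 2.00 and 36.1 ± 0.930 CPM, and Pi16 and Ly6c1 also fell. C3, the fourth, was called lower in the mean of the sorted groups but went both ways, at 270.4, 451 and 55.2 CPM. The group rose (median 2.10, camera, Benjamini-Hochberg adjusted p = 5.9e-05, and adjusted p = 0.169 with an estimated correlation). Of 17 measured genes of the NF-kB and IL-1 response, 15 rose, 1 fell and 1 did not pass the test (the same numbers adjusted over the list alone). Ptgs2, which encodes an enzyme of prostaglandin synthesis, stood at 99.4, 2467 and 3836 CPM; the member called lower in the mean was Vcam1, an adhesion molecule gene, at 593, 776 and 214 CPM. The group test gave a median of 1.96 (camera, Benjamini-Hochberg adjusted p = 8.4e-07, and adjusted p = 0.135 with an estimated correlation). Of 12 complement genes, 5 rose, 5 fell and 2 did not pass the test (the same numbers adjusted over the list alone), with C1s1 higher. That list did not pass as a group (median -0.14, camera, Benjamini-Hochberg adjusted p = 0.631).

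Antigen presentation genes went in different directions. Of the 13 genes on the MHC class II presentation list, 6 had enough counts to be tested, and of these 3 rose, 2 fell and 1 did not pass the test (the same numbers adjusted over the list alone). H2-Ab1, the beta chain of the I-A molecule, stood at 5.24 ± 1.43, 34.7 ± 3.95 and 49.8 ± 6.05 CPM in parental, BMFA3 and CT1BA5 cells, and H2-Eb1, the beta chain of the I-E molecule, at 79.3 ± 0.625, 21.6 ± 0.970 and 23.6 ± 3.33 CPM. Cd74, the invariant chain gene, stood at 2.00 ± 0.860, 5.36 ± 0.00497 and 2.20 ± 0.188 CPM; its rise in the mean of the sorted groups (log2 0.80 ± 0.27, adjusted p = 0.0118 with edgeR and Benjamini-Hochberg adjustment) was lost without parental replicate 3 (log2 0.53, adjusted p = 0.111). Over the alternatives that tested for any change, the adjusted p of Cd74 ranged from 0.00135 to 0.135 (edgeR, limma-voom or DESeq2). H2-DMb1, a peptide loading gene, rose and Ifi30, a lysosomal thiol reductase gene, fell. H2-Aa, the alpha chain partner of H2-Ab1, had at most 5 counts in a library and Ciita, the regulator of class II genes, at most 10, so neither was tested. The list as a group did not pass (median 0.50, camera, Benjamini-Hochberg adjusted p = 0.690). Among leukocyte transcripts, Ptprc, the pan-leukocyte CD45 gene, had 0 counts in every library, which allows up to 0.276 CPM (3 counts) in the library with the lowest total. Fcgr3, an Fc receptor gene of macrophages, stood at 0.286, 2.80 and 8.36 CPM.

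Of 17 measured genes of MHC class I presentation, 2 rose, 14 fell and 1 did not pass the test (the same numbers adjusted over the list alone). H2-K1 stood at 1721, 777 and 784 CPM and B2m, the light chain gene, at 2286, 1173 and 1512 CPM; H2-M3 and Psmb8 rose. Reads can be split among the near-identical class I genes, so single members are uncertain. As a group they fell (median -0.67, camera, Benjamini-Hochberg adjusted p = 0.00188, and adjusted p = 0.276 with an estimated correlation). Of 27 measured interferon response genes, 2 rose, 21 fell and 4 did not pass the test (the same numbers adjusted over the list alone). Ifit3, an antiviral gene, stood at 191, 40.1 and 28.0 CPM, and the members that rose were Ifi44 and Socs1, an inhibitor of cytokine signalling. The list's median was -0.68 (camera, Benjamini-Hochberg adjusted p = 2.2e-07, and adjusted p = 0.169 with an estimated correlation). Of 15 measured ligands that costimulate or inhibit T cells, 7 rose, 6 fell and 2 did not pass the test (the same numbers adjusted over the list alone). Nt5e, the gene of the adenosine-producing enzyme CD73, stood at 2.37, 22.1 and 179.8 CPM and Tgfb1 at 71.0, 94.3 and 361 CPM; Cd80, a costimulatory ligand gene, stood at 47.9, 26.1 and 41.2 CPM. This list as a group did not pass (median 0.23, camera, Benjamini-Hochberg adjusted p = 0.276).

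All 26 cell cycle genes fell, and all 26 were also lower adjusted over the list alone. Mki67, the proliferation marker gene, stood at 42.4, 5.95 and 1.36 CPM and Mcm5, a DNA replication helicase gene, at 91.4, 16.6 and 10.2 CPM (list median -1.85, camera, Benjamini-Hochberg adjusted p = 1.7e-18, and adjusted p = 0.0637 with an estimated correlation). Of 18 genes of cholesterol synthesis, 17 fell and 1 did not pass the test (the same numbers adjusted over the list alone), with Msmo1 at 203, 63.7 and 34.9 CPM (median -1.20, camera, Benjamini-Hochberg adjusted p = 2.2e-07, and adjusted p = 0.286 with an estimated correlation). Of 19 genes of glycolysis and hypoxia, 15 rose, 1 fell and 3 did not pass the test (16 higher and 1 lower adjusted over the list alone). Vegfa, an angiogenic growth factor gene, stood at 36.0, 192 and 438 CPM and the glycolytic gene Gapdh at 1597, 4643 and 4199 CPM; Car9, a carbonic anhydrase gene of the hypoxia response, was called lower in CT1BA5 and not in BMFA3 cells (median 1.17, camera, Benjamini-Hochberg adjusted p = 4.1e-07, and adjusted p = 0.241 with an estimated correlation).

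Of 14 glucocorticoid response genes, 5 rose, 8 fell and 1 did not pass the test (the same numbers adjusted over the list alone). Tsc22d3, Fkbp5 and Zbtb16, induced by glucocorticoid hormones, fell. Tsc22d3 stood at 274, 15.7 and 15.2 CPM, Fkbp5 at 440.2, 63.6 and 124 CPM, and Zbtb16 had a log2 fold change of -4.54 ± 0.12. The members that rose in the mean were Lcn2, Mt1 (lower in CT1BA5), Mt2, Ddit4 and Errfi1, of which metallothioneins, Lcn2 and Ddit4 also respond to metals, inflammation or stress. The group fell (median -1.06, camera, Benjamini-Hochberg adjusted p = 0.0140, and adjusted p = 0.169 with an estimated correlation). That call was lost without CT1BA5 replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.126), without CT1BA5 replicate 2 (0.0752), with no count filter (0.0600) and with the replicate number as a block (0.0649), within a range of 6.2e-06 to 0.169 over 15 alternatives. Of 9 transcription factors of the epithelial-mesenchymal transition, 7 rose, 1 fell and 1 did not pass the test (the same numbers adjusted over the list alone), with Snai2 higher and Twist1 lower (median 0.98, camera, Benjamini-Hochberg adjusted p = 0.0222, and adjusted p = 0.241 with an estimated correlation). Immediate early and heat shock genes, which can respond to tissue dissociation, were mixed. Of 21 such genes, 9 rose, 10 fell and 2 did not pass the test (the same numbers adjusted over the list alone). Junb and Ier3 rose while Dusp1 and Klf4 fell, and the list did not pass as a group (median -0.053, camera, Benjamini-Hochberg adjusted p = 0.645).

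Among genes with a mean of at least 10 CPM, Spp1, which encodes the secreted phosphoprotein osteopontin, rose from 14.1 ± 3.32 to 2668 ± 11.9 and 3358 ± 249.7 CPM. Mmp9, a gelatinase gene, and Nos2, which encodes the inducible nitric oxide synthase, had 0 counts in the parental group. Against a floor of 3 counts over that group, Mmp9 was at least 126-fold higher in BMFA3 and at least 9897-fold higher in CT1BA5 cells, and Nos2 at least 407-fold and 1307-fold. Kif21b, a kinesin gene with 3 parental counts, was 166-fold (95% interval 56.4 to 809.5) higher in BMFA3 cells. Other large increases were those of Olfm2, Crabp2, Rasl12, Cthrc1 and Aldh1a2, at 3.96, 9.61, 8.81, 7.62 and 9.14 CPM in BMFA3 cells and 230.2, 99.9, 61.5, 47.6 and 56.5 CPM in CT1BA5 cells. Leaving out 1 library moved the log2 fold changes of Rasl12 (7.35, and 8.32 without parental replicate 2), Kif21b (8.01, and 8.60 without parental replicate 3), Fam180a (-6.42, and -7.09 without CT1BA5 replicate 2) and Tmtc1 (-5.94, and -6.94 without CT1BA5 replicate 2). Cldn1, a tight junction gene, fell from 74.5 ± 5.48 to 1.14 ± 0.831 and 0.168 ± 0.128 CPM. The other large decreases were in Sult1a1, Sez6l, Itga10, Fam180a, Rapgef5, Tmtc1, Aldh1a7 and Pkhd1l1, with log2 fold changes of -6.66 to -5.51 for the last 7; Sult1a1, which overlaps Sgf29, was at least 369-fold lower in CT1BA5 cells.

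Most markers of other cell types had too few counts to be tested. Of 14 lymphocyte and 8 islet markers none was tested, with at most 10 and 6 counts in a library. Epcam, a gene of epithelial and carcinoma cells, had at most 5 counts, and Cd86 at most 1. Of 6 tested macrophage markers, 3 rose and 3 did not pass the test (the same numbers adjusted over the list alone), with Fcgr3 at 0.286, 2.80 and 8.36 CPM (median 0.31, or 0.64 with genes of a group at 0 set to their bound, camera, Benjamini-Hochberg adjusted p = 0.276). S100a8, the neutrophil gene with enough counts, had 0 counts in parental cells and 5.39 and 1.71 CPM in sorted cells. Of 4 endothelial markers, 1 rose and 3 fell (the same numbers adjusted over the list alone), Kdr among the latter (median -0.89, camera, Benjamini-Hochberg adjusted p = 0.0882). This list passed without parental replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.0249), without BMFA3 replicate 1 (0.0498), without rRNA-linked genes (0.0370) and by fry (5.4e-05), 4 of 15 alternatives in a range of 5.4e-05 to 0.477. Of 7 tumour epithelium markers, 3 rose, 1 fell and 3 did not pass the test (the same numbers adjusted over the list alone), with Krt20 at 0.694, 1.55 and 4.23 CPM (median 0.69, camera, Benjamini-Hochberg adjusted p = 0.624). Of 5 pericyte and stellate cell markers, 3 rose, 1 fell and 1 did not pass the test (the same numbers adjusted over the list alone), with Rgs5 higher (median 1.52, camera, Benjamini-Hochberg adjusted p = 0.265). Of 3 adipocyte markers, 1 fell and 2 did not pass the test (the same numbers adjusted over the list alone), Lpl being lower (median -0.61, camera, Benjamini-Hochberg adjusted p = 0.146). Only 1 or 2 members were tested in the dendritic cell (Ccr7 higher, Zbtb46 lower), acinar (Cela1 higher) and erythroid (Alas2 lower) lists, too few for a group test.

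With edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4797 genes were higher and 4802 lower in sorted cells among 13784 tested, and 983 and 1387 changed by more than 2-fold. With library sizes alone, in place of TMM scaling, the median of all genes moved to -0.15 (log2) and the split became 3600 higher and 5964 lower. Of 23 lists tested by camera, 7 were higher and 6 lower; with an estimated correlation camera called 0 (3 higher and 3 lower at an unadjusted p under 0.05), and fry called 10 in each direction. Sorted cells came from tumours and through flow sorting and parental cells did not, so growth site, surroundings and handling cannot be separated. The labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

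**Figure D2:**
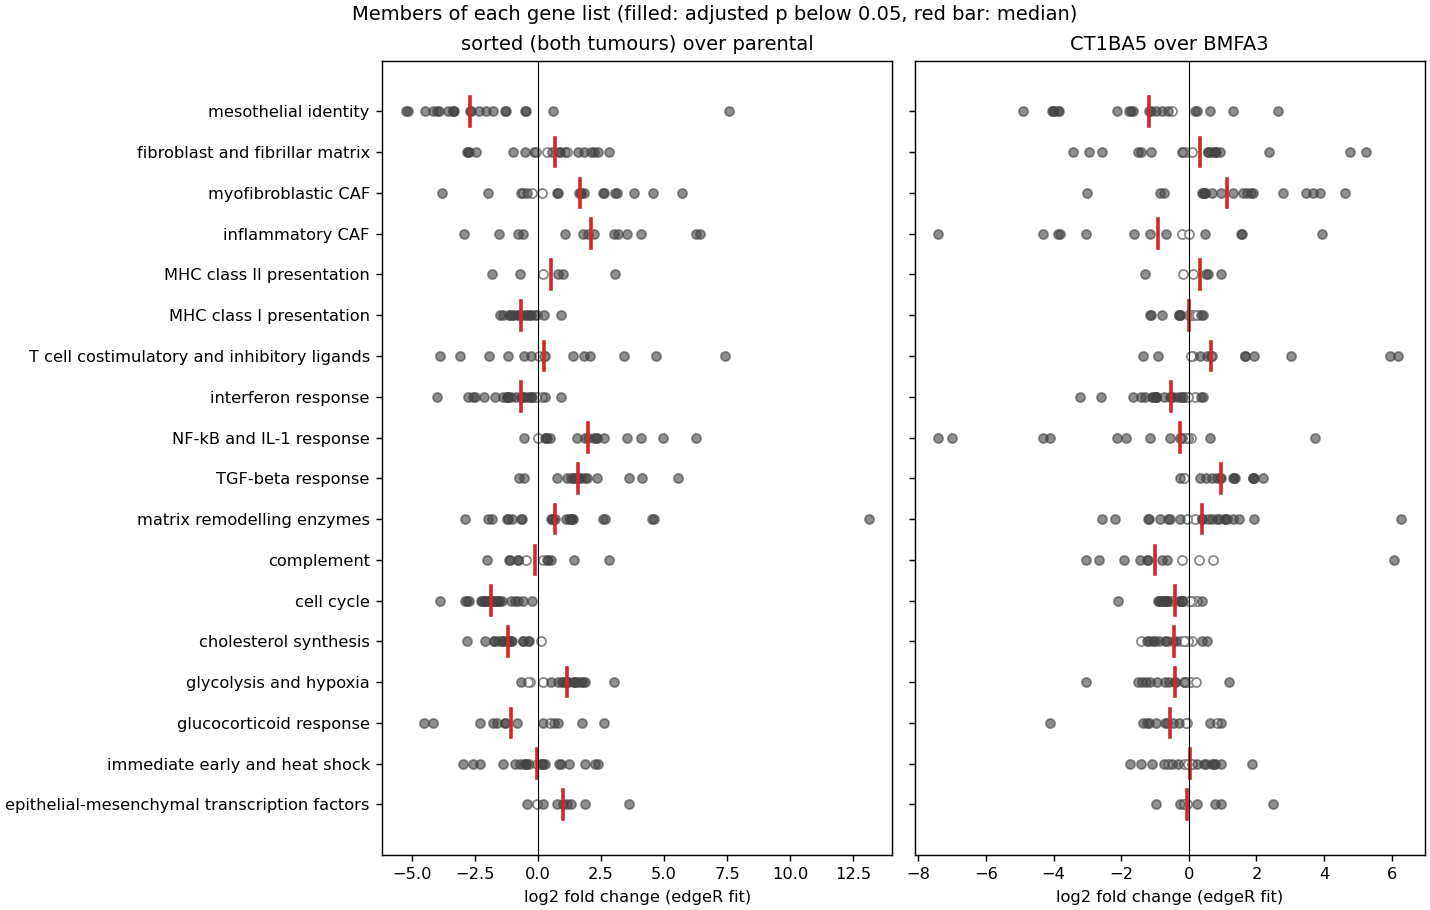
Log2 fold changes of the measured members of 18 gene lists, for sorted over parental cells and for CT1BA5 over BMFA3 cells. Each point is a gene, filled where it passed an adjusted p of 0.05, and the red bar is the list's median, such as -2.69 for mesothelial identity and 1.58 for the TGF-beta response over parental cells; the highest point is Mmp9, whose fitted value depends on the prior count.

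The second comparison took cells from BMFA3 tumours alone against parental cells. Il6, Saa3 and Cxcl1 were among the genes with the largest increases. Il6 rose 82.3-fold, to 88.7 ± 2.18 CPM (n = 2), Saa3, an acute-phase gene, from 1.83 ± 0.412 to 109.8 ± 2.53 CPM, and the neutrophil chemokine gene Cxcl1 from 2.11 ± 0.0988 to 108 ± 3.54 CPM. Lcn2, which encodes an iron-binding acute-phase protein, rose from 7.39 ± 0.138 to 189 ± 4.26 CPM and Spp1 rose 191-fold. Msln, Upk3b and Krt19 fell 8.16-, 8.78- and 10.2-fold, whereas Wt1 stood at 252 ± 19.5 in parental and 257 ± 6.77 CPM in BMFA3 cells (edgeR, Benjamini-Hochberg adjusted p = 0.773).

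Of 14 inflammatory CAF genes, 11 rose and 3 fell (the same numbers adjusted over the list alone) (median 2.57, camera, Benjamini-Hochberg adjusted p = 4.5e-11, and adjusted p = 0.0441 with an estimated correlation). Members that fell included Pi16 and Ly6c1. Of 17 NF-kB and IL-1 response genes, 15 rose and 2 did not pass the test (the same numbers adjusted over the list alone) (median 1.83, camera, Benjamini-Hochberg adjusted p = 2.4e-15, and adjusted p = 0.0414 with an estimated correlation). Cxcl1, Il6, Ccl2 and Saa3 belong to both lists, Lcn2 to the NF-kB and glucocorticoid lists, and Tgfb1, Snai1, Snai2, Junb and Ccn2 to more than 1 list. Of 16 TGF-beta response genes, 13 rose, 2 fell and 1 did not pass the test (the same numbers adjusted over the list alone) (median 1.19, camera, Benjamini-Hochberg adjusted p = 1.1e-09, and adjusted p = 0.0414 with an estimated correlation). In the myofibroblastic list Acta2 rose 3.40-fold and the collagen gene Col8a1 fell. Of 20 members, 13 rose, 5 fell and 2 did not pass the test (13 higher and 6 lower adjusted over the list alone) (median 0.94, camera, Benjamini-Hochberg adjusted p = 0.00102, and adjusted p = 0.0832 with an estimated correlation). Mmp2, the gene of a gelatinase, rose with a log2 fold change of 2.11 ± 0.069 (SE). Of 23 matrix remodelling enzymes, 15 rose, 7 fell and 1 did not pass the test (the same numbers adjusted over the list alone) (median 0.48, camera, Benjamini-Hochberg adjusted p = 0.00319, and adjusted p = 0.176 with an estimated correlation). Pdgfra, a growth factor receptor gene of fibroblasts, rose from 8.85 ± 0.784 to 52.2 ± 1.98 CPM. Of 20 fibroblast and fibrillar matrix genes, 8 rose, 8 fell and 4 did not pass the test (the same numbers adjusted over the list alone), and the group did not pass (median 0.29, camera, Benjamini-Hochberg adjusted p = 0.444).

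Mesothelial genes fell in this group. Of 21 measured, 2 rose, 17 fell and 2 did not pass the test (the same numbers adjusted over the list alone) (median -1.75, camera, Benjamini-Hochberg adjusted p = 2.7e-12, and adjusted p = 0.176 with an estimated correlation), and Pdpn and Aldh1a2 were the members that rose. H2-Ab1 rose to 34.7 ± 3.95 CPM, Cd74 to 5.36 ± 0.00497 and H2-DMb1 to 46.0 ± 4.13, and H2-Eb1 fell to 21.6 ± 0.970 CPM. Of 6 class II genes, 3 rose, 2 fell and 1 did not pass the test (the same numbers adjusted over the list alone) (median 0.50, camera, Benjamini-Hochberg adjusted p = 0.918). H2-K1 fell to 777 ± 11.1 CPM and Ifit3 to 40.1 ± 3.11 CPM. Of 17 class I genes, 2 rose, 12 fell and 3 did not pass the test (the same numbers adjusted over the list alone) (median -0.76, camera, Benjamini-Hochberg adjusted p = 0.00342, and adjusted p = 0.305 with an estimated correlation). Of 27 interferon response genes, 4 rose, 20 fell and 3 did not pass the test (the same numbers adjusted over the list alone) (median -0.55, camera, Benjamini-Hochberg adjusted p = 3.7e-05, and adjusted p = 0.176 with an estimated correlation).

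Mki67 fell to 5.95 ± 0.489 CPM and Msmo1 to 63.7 ± 5.10 CPM. All 26 cell cycle genes fell, the same number adjusted over the list alone (median -1.68, camera, Benjamini-Hochberg adjusted p = 1.8e-20, and adjusted p = 0.0414 with an estimated correlation). Of 18 cholesterol synthesis genes, 16 fell and 2 did not pass the test (the same numbers adjusted over the list alone) (median -0.95, camera, Benjamini-Hochberg adjusted p = 3.2e-07, and adjusted p = 0.305 with an estimated correlation). Gapdh rose 2.91-fold and Vegfa 5.33-fold. Of 19 glycolysis and hypoxia genes, 17 rose and 2 did not pass the test (the same numbers adjusted over the list alone) (median 1.41, camera, Benjamini-Hochberg adjusted p = 1.2e-11, and adjusted p = 0.176 with an estimated correlation). Tsc22d3 fell 17.4-fold. Of 14 glucocorticoid response genes, 5 rose, 8 fell and 1 did not pass the test (the same numbers adjusted over the list alone) (median -0.68, camera, Benjamini-Hochberg adjusted p = 0.0425, and adjusted p = 0.176 with an estimated correlation). Snai1 rose to 58.8 ± 1.08 CPM. Of 9 epithelial-mesenchymal factors, 5 rose, 1 fell and 3 did not pass the test (the same numbers adjusted over the list alone) (median 0.64, camera, Benjamini-Hochberg adjusted p = 0.0145, and adjusted p = 0.176 with an estimated correlation). Of 4 endothelial markers, at low levels, 1 rose, 2 fell and 1 did not pass the test (1 higher and 3 lower adjusted over the list alone) (median -0.84, camera, Benjamini-Hochberg adjusted p = 0.0474, and adjusted p = 0.176 with an estimated correlation).

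C3, the central complement gene, and Serping1, which encodes the C1 inhibitor, rose (log2 0.74 ± 0.086 and 0.97 ± 0.080). Of 12 complement genes, 5 rose, 4 fell and 3 did not pass the test (the same numbers adjusted over the list alone) (median 0.27, camera, Benjamini-Hochberg adjusted p = 0.221). Of 15 genes on the T cell ligand list, 5 rose, 8 fell and 2 did not pass the test (the same numbers adjusted over the list alone). Their median was -0.44 and their mean -0.015, opposite in sign to the camera direction, which was up (camera, Benjamini-Hochberg adjusted p = 0.999).

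By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4020 genes were higher and 4115 lower, 785 and 921 by more than 2-fold. With library size alone the median of all genes was -0.071 and the split 3444 higher to 4672 lower. Camera called 7 lists higher and 7 lower, and with an estimated correlation 4 of these 14 calls held. With 2 sorted libraries the largest decreases rest on few counts: the log2 fold change of Cldn1 was -6.05, and -7.06 without BMFA3 replicate 2.

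The third comparison took cells from CT1BA5 tumours against parental cells. Acta2 rose 11.1-fold to 1713 ± 112 CPM (n = 2), Col1a1 4.07-fold to 5328 ± 173 and Tnc 50.5-fold to 1368 ± 169.9 CPM. Lox reached 7185 ± 550.3 CPM. Among mesothelial genes Upk3b was 146-fold lower at 20.4 ± 0.835 CPM and Lrrn4, a leucine-rich repeat gene of the mesothelium, at 0.991 ± 0.520 CPM. The log2 fold change of Lrrn4 was -6.02 ± 0.19, and -6.73 without CT1BA5 replicate 1.

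Of 20 myofibroblastic CAF genes, 15 rose, 4 fell and 1 did not pass the test (15 higher and 5 lower adjusted over the list alone) (median 1.97, camera, Benjamini-Hochberg adjusted p = 4.9e-11, and adjusted p = 0.0199 with an estimated correlation). Ccn2, a matricellular growth factor gene, rose with a log2 fold change of 2.63 ± 0.064 (SE). Of 5 pericyte and stellate cell markers, 5 rose (the same numbers adjusted over the list alone), and the group did not pass (median 1.66, camera, Benjamini-Hochberg adjusted p = 0.0559), while fry gave an adjusted p of 7.9e-05. Of 6 macrophage markers, 4 rose and 2 did not pass the test (the same numbers adjusted over the list alone) (median 0.51, camera, Benjamini-Hochberg adjusted p = 0.322). Of 16 TGF-beta response genes, 14 rose and 2 fell (the same numbers adjusted over the list alone), the latter Col4a1 and Col4a2 (median 2.09, camera, Benjamini-Hochberg adjusted p = 5.2e-20, and adjusted p = 0.0199 with an estimated correlation). Of 23 matrix remodelling enzymes, 15 rose and 8 fell (the same numbers adjusted over the list alone) (median 0.93, camera, Benjamini-Hochberg adjusted p = 1.1e-04, and adjusted p = 0.0945 with an estimated correlation). Of 20 fibroblast and fibrillar matrix genes, 12 rose, 6 fell and 2 did not pass the test (the same numbers adjusted over the list alone) (median 0.52, camera, Benjamini-Hochberg adjusted p = 0.626). Of 21 mesothelial identity genes, 2 rose and 19 fell (the same numbers adjusted over the list alone) (median -3.64, camera, Benjamini-Hochberg adjusted p = 5.2e-20, and adjusted p = 0.0945 with an estimated correlation). Il6 and Il11 rose and Saa3 and C3 fell. Of 14 inflammatory CAF genes, 8 rose, 5 fell and 1 did not pass the test (the same numbers adjusted over the list alone) (mean 1.32, camera, Benjamini-Hochberg adjusted p = 8.5e-06, and adjusted p = 0.120 with an estimated correlation). Of 17 NF-kB and IL-1 response genes, 12 rose, 2 fell and 3 did not pass the test (the same numbers adjusted over the list alone) (median 0.58, camera, Benjamini-Hochberg adjusted p = 4.5e-04, and adjusted p = 0.120 with an estimated correlation).

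Among genes of the T cell ligand list Nt5e rose 73.1-fold and Tgfb1 5.08-fold, and Cd40, a receptor gene with 0 parental counts, was at least 182-fold higher. Of 15 such genes, 8 rose, 5 fell and 2 did not pass the test (the same numbers adjusted over the list alone) (median 0.86, camera, Benjamini-Hochberg adjusted p = 7.5e-04, and adjusted p = 0.120 with an estimated correlation). H2-Ab1 rose to 49.8 ± 6.05 CPM while H2-Eb1 fell to 23.6 ± 3.33 CPM. Cd74 stood at 2.20 ± 0.188 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.684). Of 6 class II genes, 2 rose, 2 fell and 2 did not pass the test (the same numbers adjusted over the list alone) (median 0.14, camera, Benjamini-Hochberg adjusted p = 0.537). Of 17 class I genes, 2 rose, 11 fell and 4 did not pass the test (the same numbers adjusted over the list alone) (median -0.72, camera, Benjamini-Hochberg adjusted p = 0.0105, and adjusted p = 0.309 with an estimated correlation). Of 27 interferon response genes, 3 rose, 21 fell and 3 did not pass the test (the same numbers adjusted over the list alone) (median -0.87, camera, Benjamini-Hochberg adjusted p = 2.4e-08, and adjusted p = 0.120 with an estimated correlation). Of 12 complement genes, 2 rose, 6 fell and 4 did not pass the test (the same numbers adjusted over the list alone) (median -0.54, camera, Benjamini-Hochberg adjusted p = 0.101).

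Again all 26 cell cycle genes fell, the same number adjusted over the list alone (median -2.03, camera, Benjamini-Hochberg adjusted p = 7.9e-18, and adjusted p = 0.0744 with an estimated correlation). Of 18 cholesterol synthesis genes, 1 rose, 16 fell and 1 did not pass the test (the same numbers adjusted over the list alone) (median -1.44, camera, Benjamini-Hochberg adjusted p = 2.3e-06, and adjusted p = 0.309 with an estimated correlation). Of 19 glycolysis and hypoxia genes, 14 rose, 4 fell and 1 did not pass the test (the same numbers adjusted over the list alone), with Gapdh and Vegfa higher (median 1.17, camera, Benjamini-Hochberg adjusted p = 4.4e-04, and adjusted p = 0.309 with an estimated correlation). Of 14 glucocorticoid response genes, 4 rose, 9 fell and 1 did not pass the test (the same numbers adjusted over the list alone) (median -1.30, camera, Benjamini-Hochberg adjusted p = 1.1e-04, and adjusted p = 0.0778 with an estimated correlation). Foxc2, a forkhead factor gene, rose with a log2 fold change of 3.13 ± 0.42. Of 9 epithelial-mesenchymal factors, 6 rose, 1 fell and 2 did not pass the test (the same numbers adjusted over the list alone) (median 0.81, camera, Benjamini-Hochberg adjusted p = 0.0157, and adjusted p = 0.197 with an estimated correlation). The 3 adipocyte markers, Lpl, Pparg and Fabp4, all fell, the same number adjusted over the list alone (median -1.69, camera, Benjamini-Hochberg adjusted p = 0.0129, and adjusted p = 0.120 with an estimated correlation).

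Moxd1, Tnfrsf11b and Sprr2e were among the largest increases in this group, at least 391-, 352- and 312-fold above parental groups at 0 counts. Gucy1a1, a soluble guanylate cyclase gene, fell from 49.6 CPM to 1 count, 1409.5-fold (95% interval 253 to 55697) lower. Its fitted log2 fold change of -10.15, which depends on the prior count, was -9.17 without CT1BA5 replicate 1 and -12.57 without replicate 2. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4899 genes were higher and 4844 lower, 1284 and 1726 by more than 2-fold, and camera called 8 lists higher and 7 lower. With an estimated correlation 2 of these 15 calls held. Scaled by library size alone, the median of all genes was -0.23 and the split 3495 higher to 6280 lower.

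Changes in the sorted groups largely overlapped. Spp1, Il6, Has2 and Acta2 rose and Msln, Upk3b, Krt19 and Mki67 fell in both. In total 3061 genes were higher and 3259 lower in both, where independent lists would share 1429 and 1446. Opposite calls numbered 238 (higher in BMFA3) and 221 (lower in BMFA3), against 1413 and 1463 for independent lists. Both comparisons use the same 3 parental libraries. Simulated unchanged groups and controls (20 draws) shared a mean of 0.350 higher and 0.250 lower calls, at most 2 of each. The log2 fold changes correlated with r = 0.791 across genes, against a mean of 0.391 in the simulation. Their covariance was 1.61, or 1.57 above the simulated 0.0366. Splitting the 3 parental libraries would leave 1 of them alone, so they were not split, and part of the excess over independent lists may come from the shared controls.

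Where both sorted groups had moved, CT1BA5 cells were more often further from parental cells. Of the 3061 genes higher in both, 1384 were further in CT1BA5, 311 further in BMFA3 and 1366 not told apart by the test of CT1BA5 against BMFA3. Of the 3259 lower in both, these numbers were 1393, 224 and 1642. Median log2 fold changes were 0.69 and 0.94 for the genes higher in both, and -0.84 and -1.19 for those lower in both, in BMFA3 and CT1BA5 cells.

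The fourth comparison set cells from CT1BA5 tumours directly against cells from BMFA3 tumours, testing whether the sorted groups differed. The labels do not say that the libraries of a line are separate tumours. An effect of the tumour line therefore cannot be separated from the single tumour, animal or sort. In CT1BA5 cells 17 of 20 myofibroblastic CAF genes and 13 of 16 TGF-beta response genes were higher, and 8 of 12 complement genes and 9 of 17 NF-kB and IL-1 response genes lower. As groups these calls held with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.0269, 0.0396, 0.0396 and 0.0290). Acta2 was 3.27-fold higher in CT1BA5 cells (524 ± 12.3 against 1713 ± 112 CPM, n = 2 and 2), Tgfb1 3.83-fold and Nt5e 8.13-fold. Lrrc32, which encodes the GARP receptor that displays latent TGF-beta, went from 3.68 ± 0.892 to 132 ± 11.1 CPM. Saa3 was 170.4-fold lower in CT1BA5 cells, Cxcl1 19.8-fold and C3 8.16-fold.

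Log2 fold changes of CT1BA5 over BMFA3 cells were 1.71 ± 0.073 (SE) for Acta2, 5.17 ± 0.14 for Lrrc32 and -7.41 ± 0.18 for Saa3 (adjusted p = 2.7e-13, 2.0e-16 and 4.7e-17 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 20 myofibroblastic CAF genes, 17 rose and 3 fell (the same numbers adjusted over the list alone) (median 1.12, camera, Benjamini-Hochberg adjusted p = 8.9e-13, and adjusted p = 0.0269 with an estimated correlation). Tnc stood at 106 ± 1.67 and 1368 ± 169.9 CPM in BMFA3 and CT1BA5 cells, and Inhba at 128 ± 2.85 and 877 ± 108 CPM. Members that fell included Col15a1 and Igfbp3. Of 16 TGF-beta response genes, 13 rose, 1 fell and 2 did not pass the test (the same numbers adjusted over the list alone) (median 0.94, camera, Benjamini-Hochberg adjusted p = 2.2e-11, and adjusted p = 0.0396 with an estimated correlation). Of 15 genes on the T cell ligand list, 9 rose, 2 fell and 4 did not pass the test (the same numbers adjusted over the list alone) (median 0.66, camera, Benjamini-Hochberg adjusted p = 3.4e-07, and adjusted p = 0.0348 with an estimated correlation). Cd274, which encodes the inhibitory ligand PD-L1, and Vsir were the members that fell. Cd80 stood at 26.1 ± 0.116 and 41.2 ± 4.19 CPM. Of 23 matrix remodelling enzymes, 13 rose, 8 fell and 2 did not pass the test (the same numbers adjusted over the list alone), with Loxl1 higher and Mmp3 lower (median 0.38, camera, Benjamini-Hochberg adjusted p = 0.0195, and adjusted p = 0.360 with an estimated correlation). Mcam, an adhesion molecule gene of pericytes, was higher (log2 1.72 ± 0.11). Of 5 pericyte and stellate cell markers, 2 rose and 3 did not pass the test (the same numbers adjusted over the list alone) (median 0.28, camera, Benjamini-Hochberg adjusted p = 0.0162, and adjusted p = 0.134 with an estimated correlation).

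Lcn2 stood at 189 ± 4.26 and 10.9 ± 2.03 CPM in BMFA3 and CT1BA5 cells, whereas Ptgs2 rose from 2467 ± 56.5 to 3836 ± 126 CPM. Of 17 NF-kB and IL-1 response genes, 2 rose, 9 fell and 6 did not pass the test (the same numbers adjusted over the list alone) (median -0.25, camera, Benjamini-Hochberg adjusted p = 2.9e-10, and adjusted p = 0.0290 with an estimated correlation). Of 12 complement genes, 1 rose, 8 fell and 3 did not pass the test (the same numbers adjusted over the list alone), Cfi being the member that rose (median -1.01, camera, Benjamini-Hochberg adjusted p = 9.5e-06, and adjusted p = 0.0396 with an estimated correlation). Of 14 inflammatory CAF genes, 4 rose, 8 fell and 2 did not pass the test (the same numbers adjusted over the list alone), with Has2 and Il11 higher (median -0.91, camera, Benjamini-Hochberg adjusted p = 3.6e-04, and adjusted p = 0.119 with an estimated correlation). Il6 stood at 88.7 ± 2.18 and 77.2 ± 7.24 CPM (log2 -0.20 ± 0.10, adjusted p = 0.115, edgeR with Benjamini-Hochberg adjustment). Without CT1BA5 replicate 2 it passed the test at -0.30 (edgeR, Benjamini-Hochberg adjusted p = 0.0310), and with library size alone at -0.36; its adjusted p ranged from 0.00823 to 0.426 over the alternatives. Il33, an alarmin gene, fell from 60.8 ± 1.78 to 2.66 ± 0.901 CPM.

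Wt1 was lower in CT1BA5 cells (log2 -1.12 ± 0.081, SE). Of 21 mesothelial genes, 5 rose, 15 fell and 1 did not pass the test (the same numbers adjusted over the list alone) (median -1.19, camera, Benjamini-Hochberg adjusted p = 7.5e-12, and adjusted p = 0.134 with an estimated correlation). Members that rose included Krt7 and Krt8, keratin genes. H2-Ab1 was higher by 0.52 ± 0.14 (log2, adjusted p = 0.00432 by edgeR with Benjamini-Hochberg adjustment), a call lost without BMFA3 replicate 1 (0.40, adjusted p = 0.0759). H2-Eb1 did not differ past the threshold (0.12 ± 0.11), but did without CT1BA5 replicate 1 (0.27, edgeR, Benjamini-Hochberg adjusted p = 0.0466). Over the alternatives the edgeR, limma-voom or DESeq2 adjusted p ranged from 6.9e-05 to 0.0759 for H2-Ab1 and from 0.0466 to 0.894 for H2-Eb1. Cd74 was 2.44-fold lower in CT1BA5 cells. Of 6 class II genes, 3 rose, 1 fell and 2 did not pass the test (the same numbers adjusted over the list alone) (median 0.32, camera, Benjamini-Hochberg adjusted p = 0.284). Of 17 class I genes, 2 rose, 6 fell and 9 did not pass the test (the same numbers adjusted over the list alone). Their median was 0.014, their mean -0.16 and the camera direction down (camera, Benjamini-Hochberg adjusted p = 0.404). Of 27 interferon response genes, 2 rose, 18 fell and 7 did not pass the test (2 higher and 19 lower adjusted over the list alone) (median -0.52, camera, Benjamini-Hochberg adjusted p = 1.1e-05, and adjusted p = 0.175 with an estimated correlation).

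Dcn went from 213 ± 4.64 to 36.0 ± 2.90 CPM. Mfap5, a microfibril protein gene, went from 0.648 ± 0.635 to 25.5 ± 1.14 CPM. Its log2 difference, 5.24, was 6.94 without BMFA3 replicate 1 and 4.52 without replicate 2. Of 20 fibroblast and fibrillar matrix genes, 10 rose, 7 fell and 3 did not pass the test (the same numbers adjusted over the list alone). The median of that list (0.33) and its mean (0.20) were above 0 while the camera direction was down (camera, Benjamini-Hochberg adjusted p = 0.440). Of 26 cell cycle genes, 1 rose, 15 fell and 10 did not pass the test (the same numbers adjusted over the list alone) (median -0.41, camera, Benjamini-Hochberg adjusted p = 0.0162, and adjusted p = 0.428 with an estimated correlation); Rrm2, which encodes a subunit of ribonucleotide reductase, was the member that rose. Of 18 cholesterol synthesis genes, 2 rose, 9 fell and 7 did not pass the test (the same numbers adjusted over the list alone), with Dhcr7 higher (median -0.43, camera, Benjamini-Hochberg adjusted p = 0.0287, and adjusted p = 0.684 with an estimated correlation). Of 19 glycolysis and hypoxia genes, 1 rose, 11 fell and 7 did not pass the test (the same numbers adjusted over the list alone), Vegfa being the member that rose (median -0.41, camera, Benjamini-Hochberg adjusted p = 0.0287, and adjusted p = 0.676 with an estimated correlation). Of 14 glucocorticoid response genes, 2 rose, 9 fell and 3 did not pass the test (the same numbers adjusted over the list alone), with Fkbp5 higher and Mt1 lower (median -0.56, camera, Benjamini-Hochberg adjusted p = 0.00333, and adjusted p = 0.0908 with an estimated correlation). All 3 adipocyte markers fell, the same number adjusted over the list alone (median -2.15, camera, Benjamini-Hochberg adjusted p = 2.0e-04, and adjusted p = 0.0610 with an estimated correlation).

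Several lists did not pass as groups, and their medians, means and camera directions differed in sign. Of 9 epithelial-mesenchymal factors, 4 rose, 2 fell and 3 did not pass the test (the same numbers adjusted over the list alone) (median -0.049, mean 0.32, direction up, camera, Benjamini-Hochberg adjusted p = 0.526). Of 21 immediate early and heat shock genes, 8 rose, 6 fell and 7 did not pass the test (the same numbers adjusted over the list alone) (median 0.044, mean -0.0060, direction down, camera, Benjamini-Hochberg adjusted p = 0.846). Of 6 macrophage markers, 2 rose, 2 fell and 2 did not pass the test (the same numbers adjusted over the list alone) (median -0.21, mean 1.10, direction up, camera, Benjamini-Hochberg adjusted p = 0.659). Of 4 endothelial markers, 1 rose, 2 fell and 1 did not pass the test (the same numbers adjusted over the list alone) (median -0.10, mean 0.038, direction down, camera, Benjamini-Hochberg adjusted p = 0.615).

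The largest differences by the naming rule were higher in CT1BA5 cells for C1qtnf3, Prr9, Mmp9, Olfm2, Slc39a2, Mfap5, Lrrc32, Ctsw, Tfpi2 and Col5a3, with log2 fold changes of 4.50 (Col5a3) to 7.53 (C1qtnf3). They were lower for Gucy1a1, Saa3, Ddx4, Cp, Lrrn4, Adamts9, C1qtnf7, Gdpd2, Il33 and Cxcl1. Ddx4, which encodes an RNA helicase of the germ line, stood at 84.0 ± 1.67, 73.7 ± 0.776 and 0.570 ± 0.0745 CPM in parental, BMFA3 and CT1BA5 cells, and Cp, the ceruloplasmin gene, at 75.0 ± 2.68, 102 ± 2.99 and 1.43 ± 1.36 CPM. The log2 difference of Cp, -6.07, was -7.75 without CT1BA5 replicate 1, that of Lrrn4, -4.89, was -5.60 without the same library, and that of Ctsw, 5.15, was 5.91 without BMFA3 replicate 2.

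By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3521 genes were higher and 3487 lower in CT1BA5 cells, 370 and 505 by more than 2-fold; library size alone moved the median of all genes to -0.16 and the split to 2371 and 4740. Camera called 5 lists higher and 10 lower. With an estimated correlation the calls of the myofibroblastic, TGF-beta, T cell ligand, NF-kB and complement lists held here, those of the inflammatory CAF, NF-kB, TGF-beta and cell cycle lists in BMFA3, and those of the myofibroblastic and TGF-beta lists in CT1BA5. Without CT1BA5 replicate 1 the camera calls of inflammatory CAF (0.0504), glycolysis and hypoxia (0.0504), matrix remodelling (0.0846) and pericyte genes (0.0613, Benjamini-Hochberg adjusted p) were lost. That of matrix remodelling was also lost with the replicate number as a block (0.114). The ranges of these p-values over 15 alternatives were 4.6e-05 to 0.119, 0.00237 to 0.676, 2.3e-04 to 0.360 and 5.2e-04 to 0.134.

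**Figure D3:**
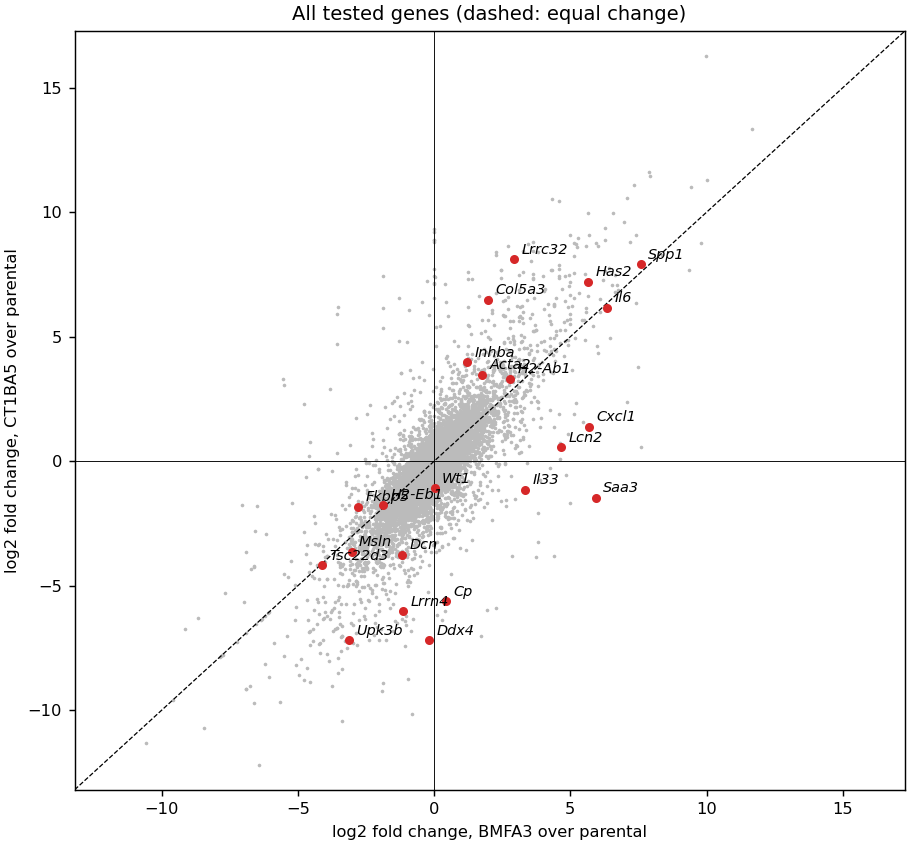
Log2 fold change over parental cells in BMFA3 (horizontal) and CT1BA5 (vertical) cells for the 13784 tested genes, with equal change on the dashed line. Genes above the line, such as Lrrc32, were higher in CT1BA5 than in BMFA3 cells, and genes below it, such as Saa3 (5.94 and -1.47), were lower.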

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

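In this part the tests of leukocytes, unchanged parental cells, scaling and culture medium were chosen only after the result was seen. Those of other splits and shared reads were not.

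The count of changed genes between sorted and parental cells was set against the other ways to split the 7 libraries into 4 and 3. Only the real split, 1 of 35, gave as many: a 2-group edgeR fit called 6221 genes, and each of the other 34 splits 0 (at most 5352 at an unadjusted p under 0.05, against 7270 for the real split). With 35 splits the share cannot fall below 1 of 35. Each of the other splits mixes libraries of different groups, which widens its spread and lowers its calls. The splits therefore cannot exclude chance, and the labels do not state that the 7 libraries are independent.

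H2-Ab1 rose while H2-Eb1, its neighbour in the class II region, fell. Leukocytes in the sorted fraction would bring their abundant transcripts along. In the mean of both sorted groups, the highest rise of 10 such transcripts, that of Cd74, was 4.81% of the 37.0 CPM rise of H2-Ab1. Cd74 rose mostly in BMFA3, at 2.00, 5.36 and 2.20 CPM in parental, BMFA3 and CT1BA5 cells. Ptprc, Tyrobp, C1qa and Aif1 had 0 counts, and H2-Aa had at most 5 counts in a library. Of 41 leukocyte markers, 21 had 0 counts in all libraries, and the highest, Fcgr3, rose by 14.3% of the mean H2-Ab1 rise. A gate on eGFP would remove such cells, but the purity of the sort was not measured here. Reads shared with paralogs are argued against as well, since 0% of the 50-base pieces of H2-Ab1 transcripts, 0 of 266 searched, occurred in transcripts of other genes. A change of class II gene use in cells from the tumour is a candidate explanation, while growth site, dissociation and medium remain untested alternatives.

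BMFA3 cells lay between parental and CT1BA5 cells on the first principal component, but the second (15.6%) set BMFA3 apart. If unchanged parental cells made up part of the BMFA3 fraction, genes nearly lost in CT1BA5 would keep a common share of their parental level, but the 90th percentile of that share was 8.82 times the 10th over 181 genes, against a median ratio of 1.11 between BMFA3 replicates. Ddx4 kept 87.7%, Lrrn4 45.8%, Msln 12.3% and Muc16 5.39%. A wrong scaling would move genes in 1 direction, whereas at least 38.9% of the shared calls of each direction lay further from parental in CT1BA5 under TMM, RLE and library size alone. The tumour line may set the extent of the change, which remains a hypothesis because it was found and tested on the same libraries and a smaller share of unchanged cells stays open. The line also cannot be separated from the single tumour, animal or sort.

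Of 14 glucocorticoid response genes 8 fell and 5 rose in sorted cells, and the fall of the list by camera was lost with an estimated correlation (Benjamini-Hochberg adjusted p = 0.169), with no count filter, with the replicate number as a block and without either CT1BA5 library. The list's median nearest 0 under RLE or library size alone was -1.06, but this cannot decide on scaling. RLE left the median of all genes almost in place (0.0061, and 0.0063 with TMM). Library size alone moved it to -0.15, in the direction of the list's fall. The labels give the same culture with 400 nM hydrocortisone for all samples, before tumours formed in the sorted groups, and the higher of the 2 tumour groups' medians was -0.68. Loss of that medium in the tumour and an effect of the tumour cannot be told apart, because surroundings change with the group and hormone levels in the tumours are not given in the sources used here. Cultured cells without hydrocortisone would be needed and were not analysed here.

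The other results here differed between the tumour lines by the test of CT1BA5 against BMFA3, in which 3521 genes were higher and 3487 lower. Log2 differences of CT1BA5 over BMFA3 follow in parentheses. Among genes fixed in advance they were positive for H2-Ab1 (0.52), Col1a1 (0.91), Acta2 (1.71), Cxcl12 (0.47) and Cd80 (0.66), and negative for Msln (-0.61), Upk3b (-4.06), Lrrn4 (-4.89), Krt19 (-1.66), Wt1 (-1.12), Cd74 (-1.29), Dcn (-2.57) and Pdgfra (-1.50). Of the 238 and 221 genes with opposite calls over parental cells in BMFA3 and CT1BA5, those among the list members named by the rule, markers of other cell types aside, were Saa3 (-7.41), Tgfb3 (1.67), Serping1 (-1.24), Vcam1 (-1.86), C3 (-3.03), Tgfb2 (1.67), Iigp1 (-1.31), Pfkfb3 (-1.26), Mt1 (-1.36) and Dnajb1 (0.78). Among the largest changes, Mmp9 (6.29), Nos2 (1.68), Kif21b (1.60), Spp1 (0.33), Aldh1a2 (2.63), Olfm2 (5.87), Crabp2 (3.38), Rasl12 (2.81), Cthrc1 (2.63), Moxd1 (3.72), Tnfrsf11b (3.55) and Sprr2e (1.25) were higher in CT1BA5, and Cldn1 (-2.60), Sez6l (-2.31), Itga10 (-1.41), Fam180a (-3.05), Rapgef5 (-1.59), Tmtc1 (-3.52), Aldh1a7 (-1.26), Pkhd1l1 (-4.20) and Cxcl1 (-4.31) were lower. Sult1a1 was at least 4.19-fold higher in BMFA3 than in CT1BA5 cells, and Gucy1a1 794-fold (95% interval 142 to 31398) higher in BMFA3.

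Lists that differed by camera, with the median log2 difference of their members, were higher in CT1BA5 for myofibroblastic CAF (1.12), T cell costimulatory and inhibitory ligands (0.66), TGF-beta response (0.94), matrix remodelling enzymes (0.38) and pericyte and stellate (0.28). They were lower for mesothelial identity (-1.19), inflammatory CAF (-0.91), interferon response (-0.52), NF-kB and IL-1 response (-0.25), complement (-1.01), cell cycle (-0.41), cholesterol synthesis (-0.43), glycolysis and hypoxia (-0.41), glucocorticoid response (-0.56) and adipocyte (-2.15). With an estimated correlation the 5 calls named in the Results held and the other 10 were lost.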

How the results depend on the processing

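The test without genes linked to ribosomal RNA was chosen only after the data were seen (4817 and 4817 genes higher and lower in sorted cells). Across the alternatives tried, no result past its threshold changed sign; the difference of H2-Eb1 between tumour lines, not called, ranged from -0.035 to 0.27. Of 226 counts 210 stayed within 1.5 times the value reported; of the values of named genes 6275 kept their side of the threshold, 94 lost and 3 gained a call, and of list results 642, 33 and 15. Testing for more than 2-fold changes lowered the counts by construction, to 983 and 1387 (both groups, higher and lower), 785 and 921 (BMFA3), 1284 and 1726 (CT1BA5) and 370 and 505 (CT1BA5 against BMFA3). A 2-group fit, whose spread includes the difference between tumour lines, called 3127 and 3094, and Lrrn4, Wt1, Cd74, Cd80, Col6a1, Col6a2 and Ifi30 were among the genes that lost their calls there. With an estimated correlation camera called 0 and 0 lists (3 and 3 at an unadjusted p under 0.05) for sorted against parental cells and 3 and 2 for CT1BA5 against BMFA3, and fry called 10 higher and 10 lower lists in the former, as fry makes no comparison with other genes. Leaving out each library gave 4286 to 4800 higher and 4426 to 4875 lower for both groups, 3330 to 4277 higher and 3345 to 4347 lower for BMFA3, 4518 to 4866 higher and 4506 to 4823 lower for CT1BA5, 2724 to 3513 higher and 2803 to 3524 lower for CT1BA5 against BMFA3 and 2597 to 3121 higher and 2762 to 3269 lower shared. Lists then ranged from 7 to 7 higher and 5 to 7 lower, and for CT1BA5 against BMFA3 from 3 to 5 higher and 8 to 10 lower, with 3 higher without CT1BA5 replicate 1; the cause was not tested. A group left with 1 library was assumed to vary like the others. Replicate numbers did not pair the libraries (correlations of deviations from group means of -0.10 to 0.077), and with the number as a block 4197 and 4297, 3472 and 3572, 4464 and 4403 and 3236 and 3242 genes and 7 and 5 and 4 and 10 lists were called. DESeq2 called 4367 and 4453 genes for both groups. Calls of Cd80 and Ifi30 in CT1BA5 and of Tcf4 between tumour lines, all small, were lost under several settings; the cause was not tested. Class II genes such as H2-Aa and Ciita, at 10 counts or fewer, could not be tested for a change at this depth. Their highest levels in a library were 0.460 and 0.609 CPM, while H2-Ab1 rose by 37.0 CPM in the mean of the sorted groups. As all genes of a library share its depth, low depth alone does not explain levels this far below that of H2-Ab1.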

Other observations

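All gene families below, and the tests of them, were chosen only after the result was seen. In all 16 families were tested, and 7 passed by camera for sorted against parental cells. Of 80 cytosolic ribosomal protein genes, 78 were higher in sorted than in parental cells by edgeR (median log2 fold change 0.97, or 0.81 with library size alone; camera, Benjamini-Hochberg adjusted p = 1.6e-15, and adjusted p = 0.639 with an estimated correlation). Mitochondrially encoded protein genes were higher in 11 of 13 (median 0.86, or 0.71; camera, Benjamini-Hochberg adjusted p = 0.00101, and adjusted p = 0.290 with an estimated correlation). Of 31 Hox genes, which set position along the body axis, 23 rose and 1 fell (median 0.82, or 0.67; camera, Benjamini-Hochberg adjusted p = 3.4e-04, and adjusted p = 0.290 with an estimated correlation). Between the tumour lines the Hox median was 0.063 and turned to -0.10 with library size alone. Laminin genes, of the basement membrane under mesothelial cells, fell in 6 of 9 and rose in 1 (median -1.19, or -1.35; camera, Benjamini-Hochberg adjusted p = 0.0250, and adjusted p = 0.626 with an estimated correlation). Lamb2 went from 367 ± 31.5 CPM in parental to 79.9 ± 2.82 and 51.4 ± 7.42 CPM in BMFA3 and CT1BA5 cells. Keratin genes fell in 7 of 11 and rose in 3 (median -1.26, or -1.42; camera, Benjamini-Hochberg adjusted p = 0.00452, and adjusted p = 0.290 with an estimated correlation). Claudin genes fell in 3 of 5 and rose in 1 (median -5.25, or -5.41; camera, Benjamini-Hochberg adjusted p = 0.0265, and adjusted p = 0.382 with an estimated correlation). Proteasome subunit genes fell in 3 of 37 and rose in 26 (median 0.26, or 0.10; camera, Benjamini-Hochberg adjusted p = 0.00452, and adjusted p = 0.835 with an estimated correlation). The collagen, integrin, semaphorin, serpin, protocadherin, tubulin, Adam and Adamts, Slc transporter and tRNA synthetase families did not pass in this comparison (camera, Benjamini-Hochberg adjusted p from 0.538 to 0.778).

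Guidance genes of the semaphorin family were lower in CT1BA5 than in BMFA3 cells, 10 of 17, with 3 higher (median -0.90, or -1.06 with library size alone; camera, Benjamini-Hochberg adjusted p = 6.3e-05, and adjusted p = 0.169 with an estimated correlation). Sema3c stood at 841 ± 18.2, 773 ± 11.2 and 66.7 ± 4.63 CPM in parental, BMFA3 and CT1BA5 cells, and Sema3a at 231 ± 5.90, 314 ± 5.34 and 49.0 ± 2.39 CPM. In this comparison log2 fold changes correlated with transcript length at -0.34 (Spearman) across genes, and the shares of ribosomal protein and mitochondrial counts were higher in CT1BA5 libraries. Proteasome subunit genes were higher in CT1BA5 cells, 33 of 37 (median 0.54, or 0.38; camera, Benjamini-Hochberg adjusted p = 3.2e-07, and adjusted p = 0.603 with an estimated correlation). Ribosomal protein genes were higher as well, 78 of 80 (median 0.56, or 0.40; camera, Benjamini-Hochberg adjusted p = 1.8e-07, and adjusted p = 0.629 with an estimated correlation), and the other 13 families did not pass here. The families called lost their camera calls with an estimated correlation. Reads of ribosomal protein genes can be shared with their many pseudogenes, so single members are uncertain.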
